A study of Mus musculus with 12 samples.

How the data were processed

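The data were 12 chromatin immunoprecipitation libraries from mouse CD4 T helper cells, 1 for each of 6 populations and 2 histone marks. Per the labels' protocols, naive OT-II cells were cultured for 3.5 days with ovalbumin peptide and splenocytes through 2 rounds of polarization, chromatin was cut with micrococcal nuclease and sonication, and libraries of about 250 bp were amplified with 18 cycles and sequenced on a Genome Analyzer. Each deposited file lists signal values in 200 bp windows with mm9 coordinates, normalised by total tags per the file headers, and the submitters' processing notes name SICER, a caller of broad enriched regions. The aligner, the versions, the significance threshold and the control used are not given in the sources used here, nor is the constant by which tags were scaled.

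The files hold only windows in enriched regions, with a lowest listed signal of 0.2 or 0.3 depending on the library, rounded to steps of 0.1. A window that is not listed is not known to hold no tags, so such features are described as listed at 0 and no fold is printed against them. Counts of features apart by 2-fold on the log2(signal + 1) scale do include features listed at 0 on the lower side. Because signal is a multiple of the value of 1 tag before rounding, that value was estimated from how many tag numbers fall in each step of 0.1. It could be read in 10 of the 12 files and in neither ex vivo file. On simulated files with known tag values, all 36 were recovered within 3%. Those modelled on the ex vivo files were recovered too, unlike the real ones, so the simulated files were easier to read than real files. Their tag values spanned less than the values read, so the lowest and highest readings were not checked. Listed tags are the summed signal divided by this value, and leave out tags outside the listed windows. A scaled signal of 5 stood for 41.9 to 161 tags in those 10 libraries. PCR copies were not marked, so intervals and counting errors cover counting only.

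The planned unit was tags over promoters. The files hold signal and no tags, and the gene table used here belongs to another build, GRCm38, so no gene was placed on these coordinates and none is named. As the design provided for that case, the quantities were computed over the authors' regions and over 10 kb bins. The planned gene lists, promoter windows, choices of transcription start site and gene-body intervals were not run, and neither was the thinning of tags, which needs unlisted windows. Windows with at most 1 missing window between them were joined into regions. H3K4me3 was compared over the union of regions of the 6 libraries and H3K27me3 over bins. Each library's signal was divided by a median-of-ratios factor over the features with a signal of at least 5 in all 6 libraries, 14551 regions and 5276 bins. Against this scaling, medians of shared features on the deposited signal differed for H3K4me3 by a log2 ratio of 0.17 in Th1, 0.18 in Th2 and 0.14 in Th17 cells, and for H3K27me3 by -0.51 in Th1, 0.56 in Th17, -0.14 in Tfh-like and 0.34 in sorted Tfh-like cells. Scaling to the file total gave 0.45 in Th1, -0.31 in Th2, -0.34 in Tfh-like and 0.55 in ex vivo Tfh cells for H3K27me3. The planned minimum of 20 tags was replaced by a scaled signal of 5, chosen after the units were known and before any comparison was made.

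Log2 ratios used a pseudocount of 1, which understates changes of weak features. Comparisons set Th1, Th2, Th17 and Tfh-like cells each against the mean of the other 3, sorted Tfh-like against Tfh-like cells, and ex vivo Tfh against sorted Tfh-like cells. The named regions were chosen by a rule fixed before the data were examined, the 5 highest and 5 lowest ratios of each comparison and mark, and the text gives those that differ most in kind. With 1 library per group there was no test and no p-value. Overlap was measured as the Jaccard index of listed windows and as the share of regions overlapped by at least 1 window. H3K27me3 over regions that differ in H3K4me3 was set against 10000 random lists matched in 20 classes of mean H3K27me3 level. Mitochondrial windows were left out of all comparisons.

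On simulated tags for the 49253 H3K4me3 regions, each of the 6 comparisons recovered 100 of 100 regions changed 3-fold and 100 of 100 changed 5-fold, and called 0 of 20475 unchanged ones. The simulation holds counting error only and no differences between preparations. It also leaves out the listing of windows, so the 0 false calls say nothing about features that are listed at 0 in one library. Alternatives chosen in advance were regions above the library's median signal, windows up to 600 bp apart merged, 50% of a region covered, scaling to the file total and no minimum signal. Added after seeing the data were a common floor of 0.3, an equal number of strongest windows in each library (243919 for H3K4me3 and 306246 for H3K27me3), signal as deposited, pseudocounts of 0.5 and 5, bins of 5 kb and 20 kb, regions extended by 1000 bp or 5000 bp, and leaving out chromosomes X and Y. The comparisons of regions listed in 1 lineage and of H3K27me3 at H3K4me3 regions were also added after seeing the data. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.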

Results

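Trimethylation of histone H3 at lysine 4 (H3K4me3), a mark of active and poised promoters, and at lysine 27 (H3K27me3), a mark laid down by the Polycomb system at silent genes, was profiled by chromatin immunoprecipitation and sequencing in 6 populations of mouse CD4 T helper cells. Naive T cells carrying the OT-II transgenic receptor, which recognises an ovalbumin peptide, were cultured towards the Th1, Th2, Th17 and follicular helper-like (Tfh-like) fates, and another library pair came from Tfh-like cells sorted for the chemokine receptor CXCR5 and the inhibitory receptor PD-1. The remaining pair came from follicular helper (Tfh) cells taken without culture from spleens of immunized C57BL6/J mice, 6 days after sheep red blood cells were given. There was 1 library per population and mark, 12 in all, so no difference below has a replicate check and no test was made. The questions, as far as the labels and the series title give them, were how the marks differ between the helper fates and how closely cultured follicular cells match those formed in the animal.

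H3K4me3 covered between 48.8 Mb in ex vivo Tfh cells and 83.7 Mb in Th1 cells, in 28824 to 38522 regions. H3K27me3 had lower signal per window and covered more of the genome than H3K4me3 in every population except Th1: 61.2 Mb in Th1 cells, 103 Mb in ex vivo Tfh cells, 164 Mb in Th2, 170 Mb in Tfh-like, 179 Mb in Th17 and 227 Mb in sorted Tfh-like cells. The mean signal per listed window of H3K4me3 was 1.98 in Th1, 1.96 in Th2, 2.24 in Th17, 1.39 in Tfh-like, 2.30 in sorted Tfh-like and 1.27 in ex vivo Tfh cells. For H3K27me3 it ranged from 0.353 in sorted Tfh-like to 0.511 in Th1 cells. The listed windows held 10900000 to 14700000 tags in the 5 cultured H3K4me3 libraries and 7120000 to 10300000 in the Th2, Th17, Tfh-like and sorted Tfh-like H3K27me3 libraries, but 1830000 in the Th1 H3K27me3 library. In that Th1 library 1 tag was read as 0.0853 signal units, against 0.037 to 0.0426 in those 4. This was the highest reading, so it was not checked, and its misfit was 46.98 against 72.35 for values farther off. If the reading holds and all files share 1 scaling constant, the Th1 library was the shallower one. The tag value of the ex vivo libraries could not be read, and their listed tags were at least 3090000 for H3K4me3 and 2580000 for H3K27me3 if 1 tag was worth at most 0.1.

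**Figure D1:**
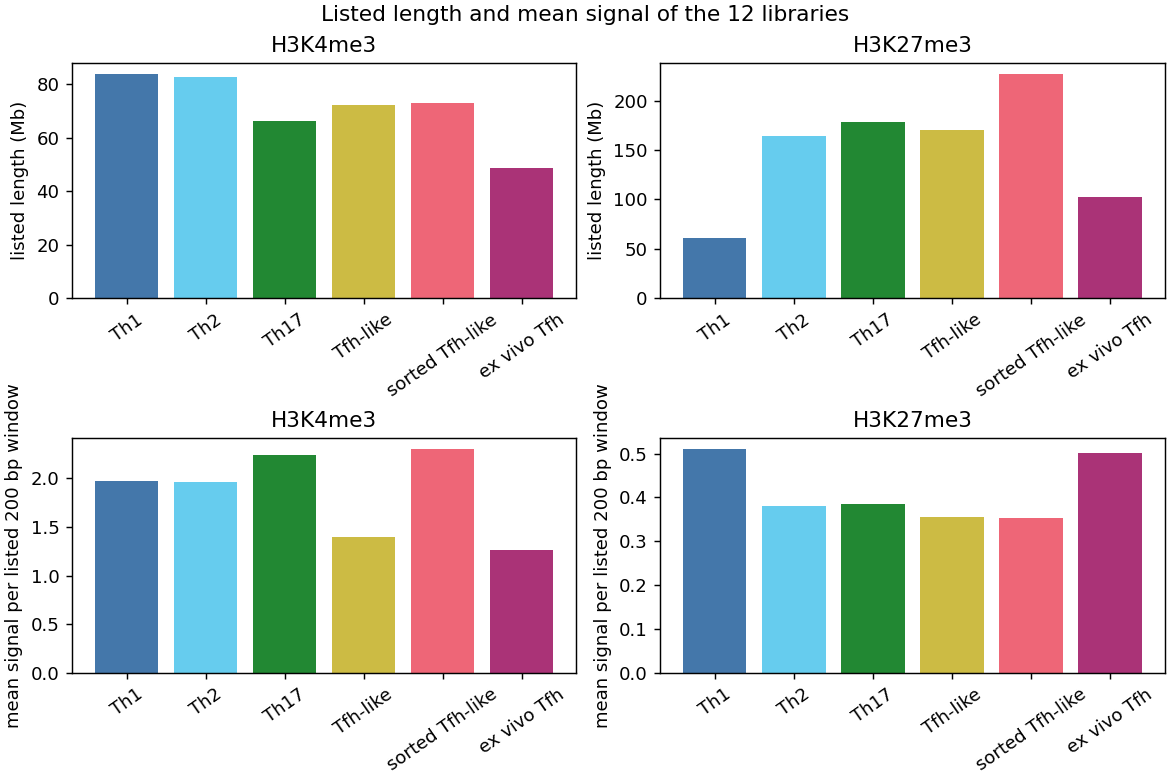
Bars give, for each of the 12 libraries, the length of genome listed in Mb (upper row) and the mean signal per listed 200 bp window (lower row), with H3K4me3 on the left and H3K27me3 on the right. The ex vivo Tfh library has the shortest H3K4me3 length, 48.8 Mb, and the Th1 library the shortest H3K27me3 length, 61.2 Mb.

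The H3K4me3 landscape was largely shared among the cultured populations, while that of ex vivo Tfh cells stood apart. Over the 10 pairs of cultures the Jaccard index of listed windows, the share of all windows of a pair that both list, lay between 62.8% (Th2 and Th17) and 73.4% (Tfh-like and sorted Tfh-like). Sorted Tfh-like cells also shared 72.4% with Th1, 70.8% with Th2 and 68.8% with Th17 cells. The top pair changed with the setting. With equal window numbers sorted Tfh-like cells shared 76.0% with Th1 and 75.4% with Tfh-like cells, and with a common floor of 0.3 they shared 73.3% and 73.0%. Ex vivo Tfh cells shared 51.7% with Tfh-like, 49.9% with Th17, 48.8% with sorted Tfh-like, 44.9% with Th2 and 44.4% with Th1 cells. The sorted follicular-like cells were thus no nearer to the ex vivo cells than the unsorted ones by this measure. Of the ex vivo H3K4me3 regions, 84.5% overlapped a region of sorted Tfh-like cells, against 86.8% for Tfh-like, 86.4% for Th1, 86.4% for Th2 and 80.8% for Th17 cells. With the same number of strongest windows kept in every library, the ex vivo library still had the lowest indices, 51.8% to 57.8%, and Tfh-like cells the highest of these.

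H3K27me3 was less alike. The highest indices were 44.1% for Tfh-like and sorted Tfh-like cells and 43.5% for Th17 and sorted Tfh-like cells, and Th2 and Th17 cells shared 41.6%. Th1 cells had low indices with all others, 17.6% to 25.7%, in the H3K27me3 library with the fewest listed windows. With equal window numbers Th1 cells no longer stood apart, with a mean index of 22.7% against 23.4% in Tfh-like and 22.4% in ex vivo Tfh cells. Ex vivo Tfh cells shared 32.7% with Th17, 31.1% with Tfh-like, 29.1% with sorted Tfh-like and 25.2% with Th2 cells, and 80.8% of their H3K27me3 regions overlapped a region of sorted Tfh-like cells. With equal window numbers the index of Tfh-like and sorted Tfh-like cells fell to 27.7%, below that of Th17 and sorted Tfh-like cells, 31.1%.

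**Figure D2:**
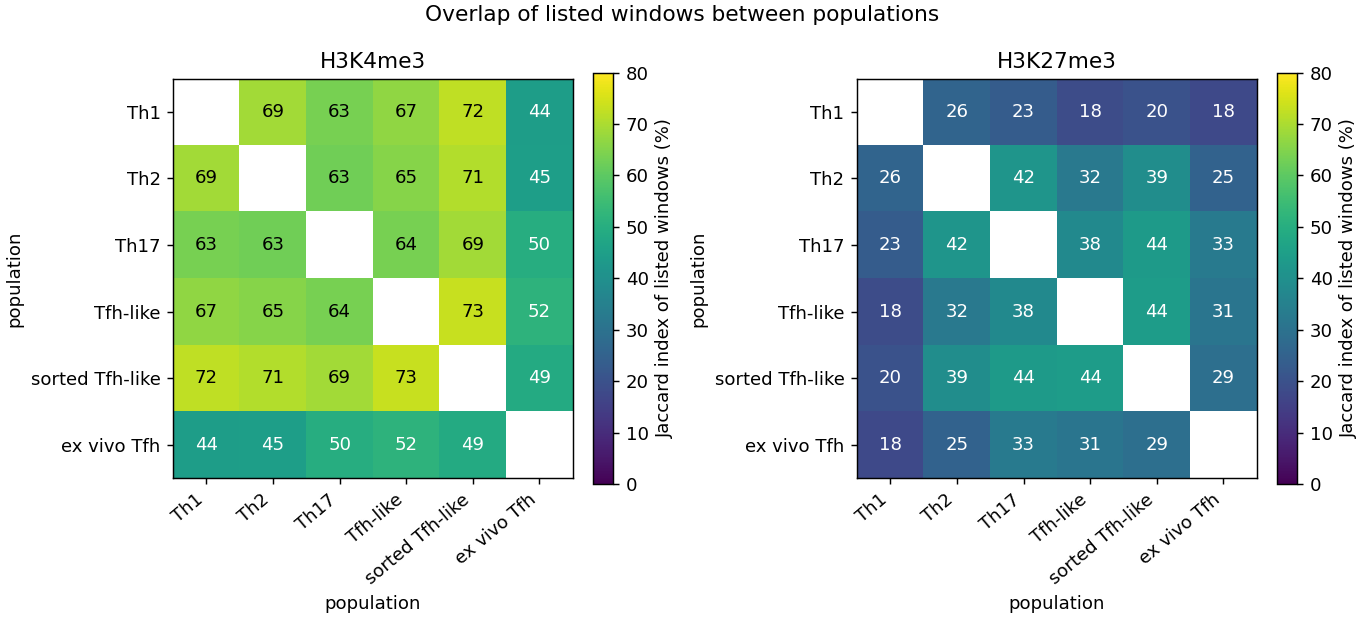
Heat maps give the Jaccard index of listed windows in percent for every pair of the 6 populations, H3K4me3 on the left and H3K27me3 on the right, on one colour scale. The ex vivo Tfh row is the lowest for H3K4me3, 44.4% to 51.7%, and the Th1 row is low for H3K27me3, 17.6% to 25.7%.

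Regions carrying both marks, a state often described at promoters that are silent but can be activated, made up the smallest share of H3K4me3 regions in Th1 cells and the largest in ex vivo Tfh cells. H3K27me3 overlapped 11.6% of H3K4me3 regions in Th1 cells (95% Wilson interval 11.3% to 11.9%), 22.6% in Th2, 23.8% in Th17, 25.2% in Tfh-like, 28.0% in sorted Tfh-like and 34.1% in ex vivo Tfh cells (33.5% to 34.6%). The intervals cover counting of regions only. An H3K27me3 region anywhere within the H3K4me3 region counted, so the marks need not lie on the same windows or in the same cells. The low Th1 share went with the H3K27me3 library that listed the fewest windows. With equal window numbers this share was 7.66%, against 32.5% in ex vivo Tfh cells. The order of the other cultures turned with the setting: with equal window numbers Th2 had 11.02%, sorted Tfh-like 13.97%, Tfh-like 15.2% and Th17 cells 15.7%. Of the 49253 regions with H3K4me3 in any population, 20563 had it in all 6, and 3011 carried both marks in all 6.

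For each fate, signal was compared with the mean of the other 3 of the Th1, Th2, Th17 and Tfh-like cultures over H3K4me3 regions and 10 kb bins of H3K27me3. A feature counted as apart at 2-fold or more with a scaled signal of at least 5 on the higher side. Th1 cells had more H3K4me3 at 1882 regions and less at 671. The largest ratios lay at chromosome X 39775201 to 39783200, with a scaled signal of 53.1 in Th1 cells, and at chromosome 13 44585201 to 44593600, with 36.6. Both were listed at 0 in the other 5 populations. The region at chromosome 10 117875201 to 117884000, reached 119 in Th1 cells, was listed at 0 in Th2 and Th17 cells, and had 14.8 in Tfh-like, 6.33 in sorted Tfh-like and 15.2 in ex vivo Tfh cells. Regions listed at 0 in Th1 cells included chromosome 7 105702201 to 105715000, with 117 in Th2, 99.03 in Th17 and 61.5 in sorted Tfh-like cells. On the signal as deposited 84.1% of the differing regions were higher in Th1 cells, against 73.7% after scaling.

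H3K27me3 of Th1 cells was higher in 1994 bins and lower in 7833, of which 3382 were listed in Th1 cells. The balance moved with the scaling and with the number of windows. Scaling to the file total gave 4928 higher and 4908 lower, the signal as deposited 770 and 11383, and equal window numbers turned the balance to 3265 higher and 1777 lower. The bin at chromosome 3 141440001 to 141450000 had 30.1 in Th1 cells and was listed at 0 elsewhere, and the bin at chromosome 2 33470001 to 33480000 was listed at 0 in Th1 cells and had 15.1 to 20.3 in the other 5 populations.

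Th2 cells had more H3K4me3 at 1802 regions and less at 805. The region at chromosome 7 89553401 to 89563400 had a scaled signal of 100.1 in Th2 cells and was listed at 0 in all other populations, and H3K27me3 was listed there in Th1, Th17, Tfh-like and sorted Tfh-like cells but not in Th2 cells. The region at chromosome 2 9484201 to 9494200 had 62.5 in Th2 cells alone. At chromosome 11 53426401 to 53433200, one of the regions listed at 0 in Th1 and in Tfh-like cells, Th2 cells had 94.3, Th17 cells 21.2, sorted Tfh-like cells 8.03 and ex vivo Tfh cells 85.4. H3K4me3 of Th2 cells was listed at 0 at chromosome 19 11515401 to 11526600, where Th1 cells had 86.5 and ex vivo Tfh cells 44.0. H3K27me3 of Th2 cells was higher in 6084 bins and lower in 1733, a share of 77.8% higher that became 64.7% with scaling to the file total. The comparator mean includes the Th1 library, which listed the fewest H3K27me3 windows, and with equal window numbers 2955 bins were higher and 1051 lower. Bins at chromosome 17 87250001 to 87260000 and 87270001 to 87280000 were listed at 0 in Th2 cells, against 23.5 and 20.1 in Th17 cells.

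Th17 cells had more H3K4me3 at 990 regions and less at 3124. The strongest gains were sharp: chromosome 3 96835001 to 96842800 had 95.1, chromosome 2 69932201 to 69939400 had 88.2 and chromosome 13 15751801 to 15761600 had 74.8, each listed at 0 in the other 5 populations. At chromosome 1 20767401 to 20788000 Th17 cells had 237, against 1.54 in Th1, 3.00 in Th2, 2.77 in Tfh-like and 6.63 in sorted Tfh-like cells, a log2 ratio of 6.11 with a counting error of 0.09. The error covers counting only. Few windows were listed there in Th1, Th2 and Tfh-like cells, and tags in unlisted windows are not known. H3K27me3 over that region was 41.8 in Th1, 28.7 in Th2, 25.9 in Tfh-like, 27.4 in sorted Tfh-like and 1.62 in ex vivo Tfh cells, and was listed at 0 in Th17 cells. Nearby H3K27me3 bins at chromosome 1 20740001 to 20750000 and chromosome 2 69900001 to 69910000 were likewise listed at 0 in Th17 cells and had 21.4 and 19.4 in Th2 cells. H3K27me3 was higher in 1699 bins and lower in 3392, but the share higher, 33.4%, became 50.6% with scaling to the file total and 79.5% on the signal as deposited.

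**Figure D3:**
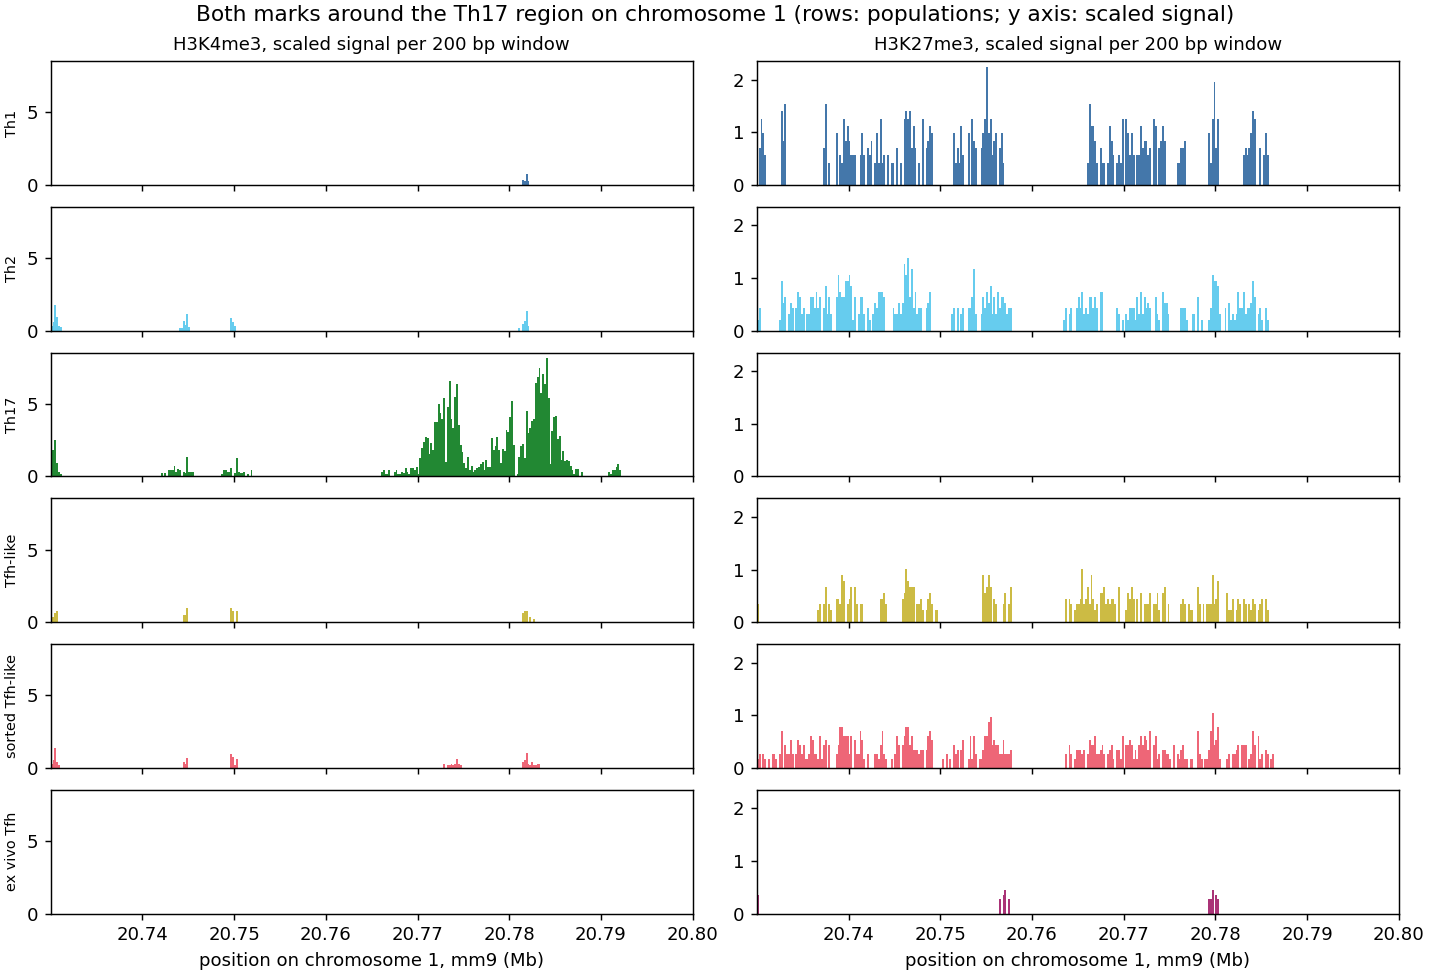
Scaled signal per 200 bp window on chromosome 1, 20730001 to 20800000 in mm9, is drawn for H3K4me3 (left) and H3K27me3 (right) with 1 row per population and one y axis per mark. Th17 cells carry H3K4me3 and no listed H3K27me3, while Th1, Th2, Tfh-like and sorted Tfh-like cells carry H3K27me3 over the same interval, and ex vivo Tfh cells list only a few H3K27me3 windows.

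Tfh-like cells had more H3K4me3 at 1836 regions and less at 1250, of which 812 were listed in Tfh-like cells. The top region, chromosome 3 37021001 to 37027800, was shared by the follicular populations only: 29.6 in Tfh-like, 32.4 in sorted Tfh-like and 12.6 in ex vivo Tfh cells, with 0 listed in Th1, Th2 and Th17 cells. H3K27me3 was listed there in Th1 cells at 8.81 and in Th2 cells at 8.78, and in ex vivo Tfh cells at 5.59. The region at chromosome 1 90108001 to 90119000, with 26.7, recurred in ex vivo Tfh cells at 56.8 and was listed at 0 in sorted Tfh-like cells, while chromosome 13 33117601 to 33121600, with 19.1, had 6.19 in sorted Tfh-like cells and was listed at 0 ex vivo. Losses included chromosome 18 65504001 to 65513000, listed at 0 in all 3 follicular populations and at 93.8 in Th17 and 63.3 in Th1 cells. On the signal as deposited 10.6% of differing regions were higher in Tfh-like cells, against 59.5% after scaling, since median levels then differed by -0.61 on the log2 scale. The balance also turned with a pseudocount of 5, to 588 higher and 737 lower, and without a minimum signal, to 5210 and 7669. H3K27me3 was higher in 10886 bins and lower in 3696, of which 2082 were listed in Tfh-like cells, giving 74.7% higher, or 59.3% with scaling to the file total. The comparator mean includes the Th1 library, which listed the fewest H3K27me3 windows. With equal window numbers 5456 bins were higher and 2410 lower. The chromosome 1 bin at 108210001 to 108220000 was listed at 0 in Tfh-like cells, against 39.2 in Th1 and 16.8 in sorted Tfh-like cells.

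Sorting for CXCR5 and PD-1 was compared with the unsorted Tfh-like culture, the nearest measure here of how far 2 libraries of one culture condition differ. These libraries also differed on chromosomes X and Y. Chromosome X held 0.415% of listed H3K27me3 signal in sorted and 1.75% in Tfh-like cells. The differences below may therefore hold more than the sort. The 14551 regions with a signal of at least 5 in all 6 libraries had a standard deviation of 0.33 in log2 ratio between them, against 0.30 for Th2, 0.31 for Th1, 0.38 for Tfh-like and 0.43 for Th17 cells, each set against a mean of 3 libraries. The sorted cells had more H3K4me3 at 341 regions and less at 1413. Gains included chromosome 6 97105601 to 97115200, with 22.7 in sorted Tfh-like, 61.6 in Th2 and 20.2 in Th1 cells, listed at 0 in Tfh-like cells. Losses were led by chromosome 1 90122001 to 90166800, with 83.8 in Tfh-like and 255 in ex vivo Tfh cells, listed at 0 in sorted cells. H3K27me3 was higher in 3925 bins and lower in 2982, which turned to 1341 and 2771 with equal window numbers and to 2713 and 3219 with a common floor of 0.3. On the signal as deposited 95.7% of differing H3K4me3 regions were higher in the sorted cells, against 19.4% after scaling, with median levels 0.75 apart on the log2 scale, and for H3K27me3 the share was 81.5% against 56.8%.

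Ex vivo Tfh cells differed from sorted Tfh-like cells at more H3K4me3 regions than in any other comparison, 4635 higher and 2854 lower, and 1064 of the lower ones were listed ex vivo. The standard deviation of log2 ratios over the 14551 regions was 0.68, above that of the sorting comparison. The largest loss was at chromosome 6 41173001 to 41178400, with 95.5 to 226 in the 5 cultured populations and 0 listed ex vivo, followed by chromosome 5 93388401 to 93397600, with 65.98 to 88.6 in the cultures. The largest gains were at chromosome 1 90122001 to 90166800, described above, and chromosome 16 3231401 to 3241600, with 90.2 ex vivo. H3K27me3 was higher in 2529 bins and lower in 14097, of which 6757 were listed ex vivo, and 41.1% of differing bins were higher with scaling to the file total, against 15.2%. The bin at chromosome 1 155160001 to 155170000 had 39.2 ex vivo and was listed at 0 in all cultures. On the signal as deposited 2.68% of differing H3K4me3 regions were higher ex vivo, against 61.9% after scaling, with median levels -1.36 apart on the log2 scale. Without a minimum signal 7549 were higher and 10690 lower.

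The marks of chromosome X and Y also differed between libraries. Chromosome X held 5.70% of listed H3K27me3 signal in Th1, 7.86% in Th2 and 7.23% in Th17 cells, against 1.75% in Tfh-like, 0.415% in sorted Tfh-like and 0.515% in ex vivo Tfh cells, while its share of H3K4me3 was 1.93% to 2.21% in all 6. Without chromosomes X and Y no count of differing features moved by over 1.5 times. Single directions moved unevenly for H3K27me3. In Tfh-like cells the higher bins went from 10886 to 10835 and the lower from 3696 to 2809. In Th2 cells the higher went from 6084 to 5101 and the lower from 1733 to 1725.

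Regions with H3K4me3 at a scaled signal of at least 5 in 1 of Th1, Th2 and Th17 cells, and none listed in the other 2, were looked up in the follicular populations. Of 345 Th1-only regions, 50.1% had H3K4me3 in Tfh-like (interval 44.9% to 55.4%), 40.6% in sorted Tfh-like and 11.9% in ex vivo Tfh cells. Of 497 Th2-only regions the shares were 16.7% (13.7% to 20.2%), 22.3% and 14.3%, and of 233 Th17-only regions 10.3% (7.02% to 14.9%), 15.9% and 9.87%. H3K27me3 lay over 23.8% of Th1-only regions in Th2 cells and 20.6% in Th17 cells, against 4.64% in Th1 cells, whose H3K27me3 library listed the fewest windows. Of Th2-only regions it lay over 18.5% in Th2 cells themselves, 12.3% in Th1 and 22.7% in Th17 cells, and of Th17-only regions over 9.01% in Th17 cells, 11.2% in Th1, 26.6% in Th2 and 33.05% in sorted Tfh-like cells. Of all 49253 regions, H3K27me3 lay over 5032 with and 1913 without H3K4me3 in Th1 cells. In Th2 cells it lay over 9163 and 3238, and in Th17 cells over 7614 and 5561. In sorted Tfh-like cells it lay over 30.9% of all regions. The shares outside the own lineage were thus near or below those of all regions, and the shares in the own lineage were below. With equal window numbers the H3K27me3 shares of Th2-only regions were 6.11% in Th2, 12.5% in Th1 and 16.1% in Th17 cells, so that Th2 cells fell below Th1 cells. Those of Th1-only regions were 1.42% in Th1, 17.9% in Th2 and 14.2% in Th17 cells, and Th17-only regions had 7.60% in Th17, 15.6% in Th1 and 23.6% in sorted Tfh-like cells. Without the minimum signal the sets held 4631, 4983 and 1736 regions, and 28.7% of Th1-only regions had H3K4me3 in Tfh-like cells. The order in Tfh-like cells turned when only regions above each library's median signal were kept, with 21.4% of Th1-only and 28.2% of Th2-only regions. With equal window numbers the Th17-only shares rose to 20.8% in Tfh-like and 17.6% in ex vivo Tfh cells, and Th2-only regions had 19.9% in Tfh-like cells.

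**Figure D4:**
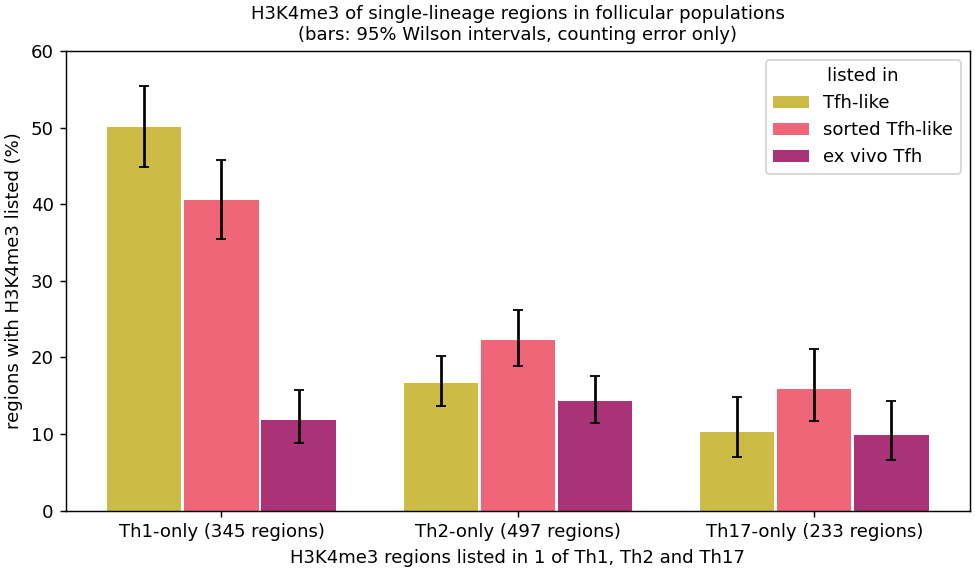
Bars give the percent of H3K4me3 regions with a scaled signal of at least 5 in 1 of Th1, Th2 and Th17 cells and none listed in the other 2 (345, 497 and 233 regions) that also had H3K4me3 listed in Tfh-like, sorted Tfh-like or ex vivo Tfh cells, with 95% Wilson intervals. Th1-only regions have the highest bars in both cultured follicular populations, 50.1% and 40.6%.

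Where a fate had more H3K4me3 and H3K27me3 was listed in any population, mean H3K27me3 was lower in Th17, Th2 and Th1 cells. Such regions were 484 of 990 in Th17, 670 of 1802 in Th2 and 650 of 1882 in Th1 cells. Of them, 77.9% had less H3K27me3 and 6.2% more in Th17 cells. The shares were 60% and 23.7% in Th2 cells, and 77.4% and 4.6% in Th1 cells. Over the 484 regions with more H3K4me3 in Th17 cells and H3K27me3 listed in any population, the mean log2 ratio of H3K27me3 was -0.93 (standard error 0.05 over regions), and the middle 95% of 10000 random lists of regions with like H3K27me3 levels lay between 0.04 and 0.15. For Th2 cells it was -0.38 (0.04) over 670 regions, against -0.06 to 0.04, and for Th1 cells -0.78 (0.03) over 650 regions, against -0.45 to -0.35. The converse held where H3K4me3 was lower in Th2 and Th17 cells, with means of 0.43 and 0.35, above their random lists. In Th1 cells the -0.43 lay among its random lists, -0.57 to -0.41, but above them with a pseudocount of 5 (-0.02 against -0.20 to -0.11), with flanks of 5000 bp and with equal window numbers. In Tfh-like cells, the culture with the lowest mean H3K4me3 signal at 1.39, 1523 of 1836 regions with more H3K4me3 had H3K27me3 listed. Their mean log2 ratio of H3K27me3 was 0.10 (0.02), above the -0.03 to 0.04 of random lists. Scaling to the file total turned this mean to -0.12, still above its random lists, -0.26 to -0.19. The 428 regions with less H3K4me3 in Tfh-like cells had 0.20, above -0.04 to 0.10, but lay within the random range with flanks of 5000 bp (0.03 against -0.13 to 0.05). The sorted cells had -0.04 (0.09) over 112 regions, against -0.01 to 0.23, but lay within the random range with flanks of 5000 bp, and their 1140 regions with less H3K4me3 had -0.07, below 0.04 to 0.11. In ex vivo Tfh cells the 3458 regions with more H3K4me3 had 0.49 (0.02), above 98.65% of random lists, whose mean was 0.46, but 0.86 within 0.81 to 0.87 with scaling to the file total. The 893 regions with less H3K4me3 ex vivo had 0.53, above 0.24 to 0.36. Regions are not replicates, and these values describe these libraries only.

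**Figure D5:**
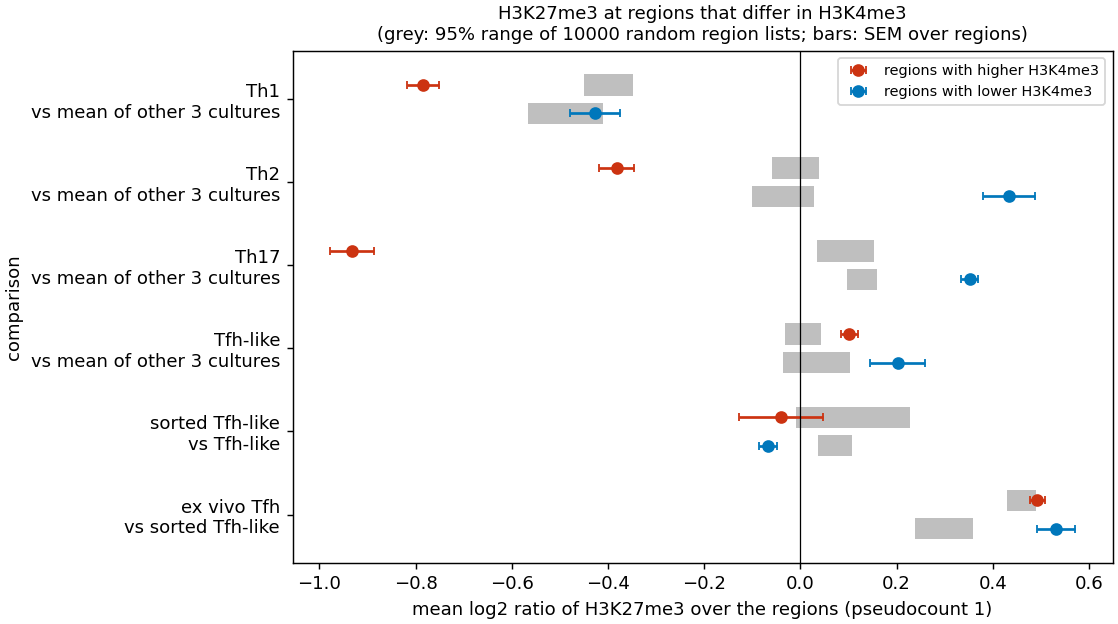
Points give the mean log2 ratio of H3K27me3 (x axis, pseudocount 1) over regions with higher (red) or lower (blue) H3K4me3 in each of the 6 comparisons (y axis), bars its standard error over regions, and grey boxes the middle 95% of 10000 random region lists. Th17 cells have the lowest red point, -0.93, far left of its box.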

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

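Mitochondrial windows were listed in the Th17 libraries and in no other, a signal outside the compared chromosomes: summed signal was 2.3 over 5 windows for H3K4me3 and 7.3 over 18 windows for H3K27me3.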

How the results depend on the processing

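Chosen after the data were seen were the 0.3 floor, equal window numbers, deposited signal, pseudocounts, bin sizes, extended regions, omission of chromosomes X and Y, and all values on lineage-only regions and on H3K27me3 at H3K4me3 regions. Tag thinning, promoter windows, other transcription start sites, gene-body intervals and gene lists were not run. No paired analysis was possible because each population and mark had 1 library. For the moved values in this part the cause was not tested, beyond what an alternative changes by construction. Values within their margin, 1.5 times for counts or the 95% interval for shares, numbered 27 for region numbers, 4 for overlap, 7 for regions with both marks, 82 for features apart and 30 for lineage-only regions; 34 values of H3K27me3 at regions with more H3K4me3 kept their side of the random lists. Values are in the order Th1, Th2, Th17, Tfh-like, sorted and ex vivo unless named.

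A floor of 0.3 broke up H3K27me3 regions, giving 134106 in Th17, 128102 in Tfh-like and 173667 in sorted cells. The Jaccard index of Tfh-like and sorted cells for H3K4me3 was 75.51% above median signal, 73.04% at the floor and 75.44% with equal windows. For H3K27me3 it was 41.27%, 39.74% and 27.74%, and 44.53% without chromosomes X and Y. That of sorted and ex vivo cells was 50.37% above median signal and 53.86% with equal windows for H3K4me3, and 27.73%, 30.13% at the floor and 23.41% for H3K27me3. With 50% of a region covered, sorted cells overlapped 82.45% of ex vivo H3K4me3 and 75.49% of H3K27me3 regions.

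The share of H3K4me3 regions with both marks was 9.575%, 18.61%, 18.08%, 20.94%, 20.9% and 28.45% above median signal. At the floor it was 10.76%, 20.26%, 21.41%, 23.11% and 25.96% in the cultures. With equal windows it was 7.656%, 11.02%, 15.67%, 15.18%, 13.97% and 32.54%. Extension by 1000 bp gave 17.63%, 31.15%, 29.74%, 31.1%, 35.53% and 38.91%, and by 5000 bp 26.89%, 44.61%, 42.46%, 42.8%, 49.27% and 50.8%. Ex vivo cells were highest and Th1 cells lowest in each of these in which they have a value.

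Features 2-fold apart without a minimum signal numbered 11004, 11360, 15189, 12879, 9077 and 18239 for H3K4me3, and 34200, 25634, 21580, 33876, 23421 and 38155 for H3K27me3. A pseudocount of 5 left 1117, 1395, 2378, 1325 and 498 H3K4me3 regions and 6019, 3401, 1936, 7560 and 2596 H3K27me3 bins in the cultures. Deposited signal gave 5018 H3K4me3 regions for Tfh-like, 4242 for sorted and 16366 for ex vivo cells, and 8063 H3K27me3 bins for Th17 cells. Equal windows gave 5042 H3K27me3 bins for Th1, 4006 for Th2, 7866 for Tfh-like, 4112 for sorted and 7358 for ex vivo cells, and bins of 5 kb gave 2798 for Th17 cells.

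Above median signal, H3K4me3 lay on 21.36%, 14.52% and 6.722% of Th1-only regions in Tfh-like, sorted and ex vivo cells, on 28.17% and 13.43% of Th2-only regions in Tfh-like and sorted cells, and on 7.763% and 5.708% of Th17-only regions in sorted and ex vivo cells. Without a minimum signal it lay on 28.65% and 19.76% of Th1-only regions in Tfh-like and sorted cells, and on 20.31%, 15.55% and 10.05% of Th2-only regions in the 3 follicular populations. With equal windows it lay on 18.01% of Th2-only regions ex vivo, and on 20.8% and 17.6% of Th17-only regions in Tfh-like and ex vivo cells. Mean H3K27me3 (log2) at regions with more H3K4me3, less that of random lists, came within the random range at 0.02 for ex vivo cells scaled to the file total and -0.1334 for sorted cells with flanks of 5000 bp. In every library a feature below the listing floor cannot be told from an empty one.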

Other observations

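Length followed how widely a region was shared. The 20563 H3K4me3 regions present in all 6 populations had a median length of 3000 bp, against 1000 bp for the 12036 present in 1. For H3K27me3 the 12332 regions present in all 6 had a median length of 8600 bp, against 1400 bp for the 39248 present in 1. A joined region grows with each library that adds windows, so part of this follows from its construction. The number of H3K4me3 regions found in a single population was 3464 for Th2, 2833 for Th1, 2454 for ex vivo Tfh, 1561 for Tfh-like, 1337 for Th17 and 387 for sorted Tfh-like cells.

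Both marks overlapped from the other side as well: H3K4me3 lay in 18.1% of H3K27me3 regions of ex vivo Tfh cells and in 11.2% to 12.3% of those of the cultures. Of the H3K4me3 regions shared by all 6 populations, 11519 had no H3K27me3 in any.

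The Th1 H3K27me3 library listed 306246 windows with a signal of 0.3 or more, against 634367 in Th17 cells, the lowest of the other cultures. Sorted Tfh-like cells listed the most H3K27me3 on the autosomes, 225 Mb.

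In the next paragraphs, the tests of mixed sexes, of differentiation and of transgene copies were chosen after the results were seen, and the other tests before. The list of explanations was also rearranged after the results were seen, with patterns merged and reworded. Dropped then were a higher listing floor and fewer tags for Th1 H3K27me3, and fewer listed windows for chromosome X.

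Chromosome X carried more H3K27me3 in Th1, Th2 and Th17 cells than in Tfh-like, sorted Tfh-like and ex vivo Tfh cells, while over 4 regions between chromosome Y 233401 and 623600 scaled H3K4me3 was 15.8 to 18.997 in Th1, Th2, Th17 and Tfh-like cells, 89.3 in sorted Tfh-like and 0 listed in ex vivo Tfh cells. Over all of chromosome Y, deposited H3K4me3 signal was 21.6 to 26.1 in Th1, Th2 and Th17, 141.3 in Tfh-like and 140.3 in sorted Tfh-like cells, and ex vivo Tfh cells listed the most H3K27me3 there, 207.8 over 247 windows. Female ex vivo and male cultured cells were predicted to give an ex vivo chromosome X share of H3K27me3 above all cultures. The share was 0.515%, below that of Th1, Th2, Th17 and Tfh-like cells, so the predicted excess was not seen. The planned test asked only whether it lay within the cultures' range. That range, 0.415% to 7.86%, was so wide that lying within it decides little. Fewer listed windows as the whole cause are argued against by 5 of 5 cultures keeping some chromosome Y windows at equal numbers. Only 9 of 39 were kept in Th1, 7 of 36 in Th2 and 16 of 39 in Th17 cells, so part of the difference may come from it. Differentiation with an unchanged mix of cells would leave chromosome Y H3K4me3 of sorted cells near that of Th1, Th2 and Th17 cells. Over the 4 regions it was 4.76 times the highest of Th1, Th2 and Th17 cells. This excess had been seen before the test was chosen, so the test cannot decide. Tfh-like cells, also low on chromosome X at 1.75%, had 18.997 over these regions against 18.8 in Th1 cells, so they showed no such excess. Different proportions of female and male cells stay open: H3K27me3 was higher in the mean of Th1, Th2 and Th17 than in sorted cells in 98.2% of 111 blocks of 1 Mb along chromosome X, but so large a difference in share would give this under other causes too. The sex of the animals is not in the labels used here, and ex vivo cells, with H3K27me3 but no H3K4me3 listed on chromosome Y, follow no single mix.

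The ex vivo comparison had the most differing H3K4me3 regions, 4635 higher and 2854 lower. Weaker enrichment of the ex vivo library may account for part: across 14551 regions, which are not independent replicates, the log2 ratio fell with level at a Spearman rho of -0.467. Tfh-like cells, with the next lowest mean signal, gave -0.246 against the other cultures. Sorted Tfh-like against Tfh-like cells gave 0.320 and Th17 cells 0.325, while Th1 cells gave 0.032 and Th2 cells -0.013. The trend may thus come in part from the sorted library and not from the ex vivo library alone. Signal that is not specific to H3K4me3 cannot be told apart from regions truly carrying both marks: of the regions higher ex vivo, 61.8% held ex vivo H3K27me3, against 29.6% of regions not 2-fold apart. That share passed the 50% set in advance as fitting unspecific signal, but the reading was changed to undecided after 65.0% of the same regions were seen to hold H3K27me3 in sorted Tfh-like cells too. A difference between cells formed in the animal and in culture stays open and untested.

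The H3K4me3 region at chromosome 6 41173001 to 41178400 was at 95.5 or more in all 5 cultures and listed at 0 ex vivo, and its H3K27me3 was listed in 5 of the 5 cultured libraries and not ex vivo. A loss through fewer listed regions is argued against, since 99.7% of the 318 regions at or above 95.5 in all 5 cultures were listed ex vivo. Extra copies of this DNA from the receptor transgene of the cultured cells stay open, since the H3K27me3 pattern was seen before this explanation was formed and does not test it. In all, 16 regions had both marks in the 5 cultures and neither ex vivo, and input DNA was not used here.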
